A study of Oryzias latipes with 4 samples.

How the data were processed

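Ribosome footprints and RNA were measured in one dissected region of female medaka (Oryzias latipes), the ventral telencephalon with the hypothalamus and the pituitary, taken 16 h after the fish were moved from the condition the labels call SD to the one they call LD. There were 4 libraries in 2 groups, 2 of LD RNA-seq and 2 of LD Ribo-seq. Ribo-seq sequences the stretches of mRNA that ribosomes protect from nuclease, so that its level relative to RNA-seq is a relative measure of translation. The libraries were made with a TruSeq Ribo Profile Mammalian kit, per the labels' protocols. All libraries came from 1 condition, so the comparison the design allows is between the assays. The labels do not say that the replicates came from separate fish, and p-values then measure only the spread between these samples, which may be technical.

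The values were FPKM (mapped fragments scaled to feature length and to the size of the library) of each library as deposited by the authors, per the file headers, for 93896 transcript models. The submitters' processing notes name TopHat2 2.1.0 and Cufflinks 2.2.1 without their roles; the genome build and the annotation are not given in the sources used here. Whether the FPKM of the footprints was computed over coding regions or over whole models is not given either; a difference between the assays then also holds any difference in the length used. Whole reads could not be recovered from the values, so the depth is unknown and no counting error is given. An FPKM of 0 can be a failed estimate, and such models are described as listed at 0. They numbered 5199 and 7139 in RNA-seq replicates 1 and 2, and 31382 and 33734 in Ribo-seq replicates 1 and 2. Of the models, 71.6% overlapped another one, and neither the strand of the models nor the use of strand in the counting is given, so that reads of overlapping or antisense models cannot be told apart. Model lengths were a multiple of 3 in 78.8% of all models, but in only 2369 of the 5698 models named and tested below. The models may thus be a mixture of coding and longer ones.

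The deposited models carry no gene names. Names were taken from the RefSeq gene table of assembly ASM223467v1 where a model and a gene each covered at least 50% of the other's span, with 1 best model per gene, and symbols that are only locus numbers were treated as unnamed. The build of the models was inferred from the data: 2137 model ends lay within 10 bp of the end of a protein-coding RefSeq gene, against a mean of 60 after moving the models by 20 kb, and the observed number was the higher one on 24 of 24 chromosomes. In all, 17796 models matched 15519 of 26832 RefSeq genes, and 7236 models received a symbol. Coordinates are those of the authors' models, written from 1. Names rest on position alone, without strand.

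Each library was divided by the median ratio of its FPKM to the model's geometric mean, over models above 0 in all 4 libraries (factors 1.40, 1.32, 0.651 and 0.925 for RNA-seq 1 and 2 and Ribo-seq 1 and 2). Models with a mean deposited FPKM of at least 1 were tested (50625, of which 5698 had a symbol). The log2 of scaled FPKM plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) with the assay as the single term, and a model was called at a Benjamini-Hochberg adjusted p below 0.05. A log2 difference is Ribo-seq minus RNA-seq on this scale, which understates the difference of low models. FPKM printed for a gene are as deposited, before scaling, so their ratio differs from the log2 difference. Their SD also holds differences in scale between libraries. FPKM of the assays cannot show an overall difference in level, so a difference of 0 means the typical ratio of the models used for scaling. Whole gene lists were compared with the other named models by camera with an inter-gene correlation of 0.01, and again with an estimated correlation, in lists with at least 5 tested members. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

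The fit was tested on simulated data. With a smooth spread and 200 changed models among 43482, it recovered 93 of 100 changed 2-fold and 100 of 100 changed 4-fold, with 7 false calls. With the scatter of spreads fitted to these libraries it recovered 0 of 200 changed models among 43739, and with 15188 of 43342 models changed it recovered 36.5% of the 2-fold and 68.6% of the 4-fold changes, with 3.76% false calls. The matched random lists of the closing section were tested on 100 simulated lists: 7 unchanged lists fell below the 5th percentile, and 96 lists lowered by 1 on the log2 scale fell below the 1st.

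The comparisons, the 26 gene lists, the alternatives and the rule for named genes were written before the data were examined. Named were, per direction, the 8 genes with the largest log2 difference among those called, with a symbol, a mean FPKM of at least 10, an FPKM above 0 in each library and no overlap between the assays' replicates; the 5 genes with the highest mean FPKM in each assay; the 3 most abundant tested members of each list with at least 3; and tshb, cga, dio2, eya3 and lpin2 where a model matched them. Members of lists with no call could be left out. From the lists, 13 symbols that the matching patterns took in by mistake were removed before values were looked at. Some others stayed in, as named below for translation factors. List medians are given relative to the median of all named models, 0.77, a form chosen after seeing the data because the scaling moves that median. Alternatives covered the pseudocount, the filter, the scaling, the replicate number as a block, the variance trend, each library left out and the correlation between genes; a fit of 1 model per RefSeq gene and names at 80% overlap were added after seeing the data.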

Results

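Ribosome footprints and RNA were profiled in the ventral telencephalon, hypothalamus and pituitary of female medaka sampled 16 h after a move from SD into LD conditions, with 2 libraries for each assay. The tissue holds the neurons and endocrine cells that control reproduction and growth. Depth is not known, since the values are FPKM. Across the 50625 tested transcript models, replicates of 1 assay were closer to each other than to the other assay: Spearman's rho was 0.91 between the RNA-seq libraries and 0.87 between the Ribo-seq libraries, and 0.46 to 0.50 between libraries of different assays. The rho of the assay means was 0.50 over these models and 0.81 over the 5698 named ones (Pearson's r on the log2 scale 0.62 and 0.83). These are correlations across genes, which are not independent replicates, and the value over all models depends on the filter (0.663 with no filter and 0.299 at a mean FPKM of at least 5).

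The most abundant named transcripts differed in part between the assays. By RNA, the highest were snap25, a protein of synaptic vesicle fusion, at 353 ± 3.23 FPKM (SD, n = 2), cirbp, an RNA-binding protein, rps15a, a ribosomal protein, calm2, a calmodulin gene, and glul, the glutamine synthetase of glia, at 264 ± 13.2. By footprints, snap25 was again highest at 2005 ± 657 FPKM (SD, n = 2). It was followed by cga, the alpha subunit shared by the pituitary glycoprotein hormones, at 1034 ± 114, ywhag, a 14-3-3 protein, at 740 ± 227, aldoc, an aldolase, at 712 ± 294, and hsc70, a chaperone, at 694 ± 286.

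Footprints were compared with RNA model by model, which asks which transcripts carry more or fewer ribosomes for their RNA level. Of the 18 lists with at least 5 tested members, respiratory chain and proteasome subunits, hypothalamic neuropeptides and pituitary hormones and markers had the highest medians. Cytosolic ribosomal proteins and ion channels and receptors had the lowest. None of these list calls held with an estimated correlation (camera, adjusted p = 0.93 for each list). Unadjusted, camera's p was then 0.28 for respiratory chain, 0.33 for proteasome, 0.47 for neuropeptide, 0.14 for pituitary, 0.53 for ribosomal protein and 0.30 for channel genes. With 2 libraries for each assay the correlation is poorly estimated. For these lists the estimate lay above the fixed correlation of the main test, from 0.019 for pituitary to 0.66 for proteasome genes. Its size is not the whole reason for weaker p-values. For developmental transcription factors the estimate, 0.0049, lay below the fixed one, yet camera's unadjusted p rose from 0.10 to 0.22. What else weakens the p-values was not tested, so the loss of a call does not show that a list does not stand apart. Of all tested models, 12116 were higher and 17048 lower in Ribo-seq (limma, adjusted p below 0.05), 9036 and 15575 of them by at least 2-fold; at an unadjusted p below 0.05 the counts were 13705 and 18501. Of the named models, 2987 were higher and 343 lower. The split depends on the scaling: with FPKM as deposited, 2425 models were higher and 21141 lower (10.3% of calls higher, against 41.5%), the median of named models moved from 0.77 to 0.13, and 480 named models were higher and 619 lower. Under all of median scaling, upper quartile scaling and no scaling, 477 named models were called higher and 343 lower. Without RNA-seq replicate 1 the counts fell to 1543 higher and 9458 lower, and without RNA-seq replicate 2 to 1529 and 9543; of the genes that the rule named, 48 and 50 then lost their call.

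Among called genes that met the abundance and overlap limits of the naming rule, the largest excess of footprints was that of nisch, uspl1, atp5md, acta2, ptrh2, snap25, mrpl33 and atf2. nisch, which encodes nischarin (model of 858 nt on chromosome 5, 890740 to 927036), had 1.26 ± 0.0939 FPKM in RNA-seq and 132 ± 8.29 in Ribo-seq (SD, n = 2). Its log2 difference was 6.47 ± 0.26 (SE, limma, adjusted p = 0.0039). At that low RNA level it met the abundance limit through Ribo-seq alone, as did ptrh2 (3.32 FPKM in RNA-seq and 30.3 in Ribo-seq). atp5md, an ATP synthase subunit (chromosome 1, 29667641 to 29673131), had 27.7 ± 2.24 FPKM in RNA-seq and 354 ± 109 in Ribo-seq. Its difference was 4.39 ± 0.13 after scaling and 3.60 with FPKM as deposited. acta2, a smooth muscle actin of vessel walls (model of 180 nt on chromosome 19, 520026 to 524505), had 66.9 ± 18.4 and 588 ± 148 FPKM, a difference of 3.92 ± 0.21. Short models may cover only part of a gene, so their values need not be those of the whole gene. The difference was 4.57 for uspl1, whose model has a tRNA gene within its span (27.4 and 23.6 FPKM in RNA-seq, 442 and 296 in Ribo-seq), so that its values can include reads of that gene. It was 3.53 for ptrh2, a peptidyl-tRNA hydrolase, 3.27 for snap25, 3.27 for mrpl33, a mitochondrial ribosomal protein, and 3.24 for atf2, a transcription factor. Each of these 8 was also called higher with FPKM as deposited.

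Among called genes that met the same limits, the largest deficit of footprints was that of stk38l, tesc, kdm7a, gins1, nrn1, fem1b, fgfbp3 and srek1. stk38l, a protein kinase gene (model of 384 nt on chromosome 23, 3868943 to 3888122), had 20.2 ± 7.17 FPKM in RNA-seq and 0.362 ± 0.225 in Ribo-seq (SD, n = 2). Its log2 difference was -3.38 ± 0.38 (SE, limma, adjusted p = 0.0053). kdm7a, a histone demethylase (chromosome 23, 17896021 to 17924064), had 45.2 ± 1.23 and 3.59 ± 0.823 FPKM, a difference of -2.61 ± 0.32. The difference was -2.77 for tesc, -2.59 for gins1, a DNA replication factor, and -2.40 for nrn1, which encodes neuritin. It was -2.32 for fem1b, -2.16 for fgfbp3 (model of 312 nt) and -1.81 for srek1, a splicing factor. All 8 were also called lower with FPKM as deposited, as were all 343 named models called lower under median scaling. Leaving out the scaling lowers the differences in general (median of named models 0.77 to 0.13), so it is not a separate check of lower calls. Without either RNA-seq library in turn, the calls of stk38l, tesc, kdm7a, gins1, nrn1, fgfbp3 and srek1, and of uspl1, snap25 and cga among the higher genes, were lost with the direction kept, and that of fem1b was lost without RNA-seq replicate 2. The models of all but uspl1, ptrh2 and atf2 among these 16 genes overlap another model, with which their reads can be shared.

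Of the 18 lists tested, genes of oxidative phosphorylation had the highest median of footprints relative to RNA. All 36 tested nuclear-encoded subunits of the respiratory chain were called higher in Ribo-seq, with a median 1.40 above that of the named models (camera, adjusted p = 6.2e-07; adjusted p = 0.93 with an estimated correlation). Among them, atp5po had 83.4 ± 2.55 FPKM in RNA-seq and 421 ± 176 in Ribo-seq (SD, n = 2), and atp5f1b 128 ± 4.29 and 339 ± 120. All 25 tested proteasome subunits were likewise called higher, with a median 1.23 above the named models (camera, adjusted p = 2.8e-05; adjusted p = 0.93 with an estimated correlation), including psmb4 (log2 difference 2.45), psmd6 (2.24) and psma8 (2.24). Adjusted over the list alone, the same counts of 36 and 25 were found. With FPKM as deposited, 22 and 12 of these members were called higher and 0 lower. The difference was larger at higher RNA levels: protein-coding models had a median of 0.70, and 1.20 at a mean RNA-seq FPKM of at least 10. At a mean FPKM of at least 5, the 2 lists lay 1.02 and 0.93 above the named models. Neither list was compared with models of matched RNA level or length, so how much of the excess goes with these was not tested. The 2 lists' own medians were 2.16 and 1.99, against 1.87 for named models matched to the RNA level of ribosomal proteins. Named models of high RNA level thus lay high too.

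Genes of pituitary and hypothalamic secretion also lay above the other named models. Of 14 tested pituitary hormones and markers, 12 were called higher and 0 lower, with a median 1.02 above the named models (camera, adjusted p = 0.031; adjusted p = 0.93 with an estimated correlation). cga had 250 ± 129 FPKM in RNA-seq and 1034 ± 114 in Ribo-seq (SD, n = 2; log2 difference 2.95 ± 0.47, SE; limma, adjusted p = 0.011). pomc, the precursor of ACTH and melanocyte-stimulating hormone, had 239 ± 11.1 and 662 ± 222 FPKM, and scg5, a protein of secretory granules, 96.6 ± 4.37 and 204 ± 68.8. Of 17 tested hypothalamic neuropeptides, 14 were called higher and 0 lower, with a median 1.17 above the named models (camera, adjusted p = 0.031; adjusted p = 0.93 with an estimated correlation). The log2 difference was 2.08 for oxt, the oxytocin-family precursor, 2.31 for cck, the cholecystokinin precursor, and 2.34 for tac1, a tachykinin precursor. Adjusted over the list alone, 12 pituitary and 15 neuropeptide members were higher. With FPKM as deposited, 5 pituitary and 7 neuropeptide members were called higher and 0 lower. These lists too were not compared with models of matched RNA level or length. Their own medians were 1.78 and 1.94, against 1.87 for named models matched to the RNA level of ribosomal proteins. Both list calls were lost at a mean FPKM of at least 5 (adjusted p = 0.15 and 0.058), and the pituitary one without Ribo-seq replicate 1 (adjusted p = 0.086).

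Translation factors lay above the median of the named models and ribosomal proteins below it, and the lists were not tested against each other. Of 33 tested members of the initiation and elongation factor list, 27 were called higher and 0 lower. Their median lay 0.38 above the named models (camera, adjusted p = 0.031; adjusted p = 0.93 with an estimated correlation). Without scaling of the deposited FPKM, 3 were called higher and 1 lower. The list's patterns also took in genes that are not such factors, among them eif4ebp1, eif4ebp2, eif4ebp3, eif4enif1 and eef1e1, which stayed in these counts. In the list, eif4a3, a helicase, had a log2 difference of 2.52 and eif5 one of 1.15. For pabpc1, the poly(A)-binding protein, it was -0.40 and did not pass the test (limma, adjusted p = 0.089). Of 62 tested cytosolic ribosomal proteins, 19 were called higher, 2 lower and 41 neither, and 7 lay above the median of the named models; with FPKM as deposited, 1 was called higher and 5 lower. The list's median was 0.47 below the named models on the log2 scale (median relative to them -0.47; camera, adjusted p = 0.031; adjusted p = 0.93 with an estimated correlation), and its own median of 0.29 turned to -0.50 with FPKM as deposited. rpl36 had 210 ± 3.06 FPKM in RNA-seq and 273 ± 78.9 in Ribo-seq (SD, n = 2). In the same order, rps15 had 209 ± 16.5 and 192 ± 67.1, and rps15a had 299 ± 24.8 and 271 ± 98.2. Their log2 differences were 1.15, 0.64 and 0.62, of which the latter 2 turned negative with FPKM as deposited. That setting lowered named models in general (median 0.77 to 0.13), so such turns are not particular to these genes. Relative to named models, the list's median was then -0.63. Adjusted over the list alone, 28 members of the factor list were higher, and 12 ribosomal proteins were higher and 1 lower. The factors lost their list call with FPKM as deposited (adjusted p = 0.11), at a mean FPKM of at least 5 (0.49), and without Ribo-seq replicate 1 (0.086) or 2 (0.062). The ribosomal proteins lost theirs with no filter (adjusted p = 0.45) and without Ribo-seq replicate 1 (0.25).

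Ion channels and neurotransmitter receptors had a median below that of the named models, with 8 of 21 tested members above it. Of these 21, 7 were called higher, 4 lower and 10 neither, the same counts as adjusted over the list alone, with a median of -0.35 relative to the named models (camera, adjusted p = 0.031; adjusted p = 0.93 with an estimated correlation). With FPKM as deposited, 1 was called higher and 6 lower. The median itself, 0.41, then turned to -0.22, while relative to the named models it stayed at -0.35. The glial potassium channel gene kcnj10 had a log2 difference of 1.18 and kcnk1 one of 1.26, both above the median of the named models, and scn3b, a sodium channel subunit, one of 0.20 that did not pass the test and turned negative with FPKM as deposited. The channel list lost its call with upper quartile scaling (adjusted p = 0.058), the replicate number as a block (0.064), no filter (0.057), a mean FPKM of at least 5 (0.32), 1 model per RefSeq gene (0.10) and without Ribo-seq replicate 1 (0.086).

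**Figure D1:**
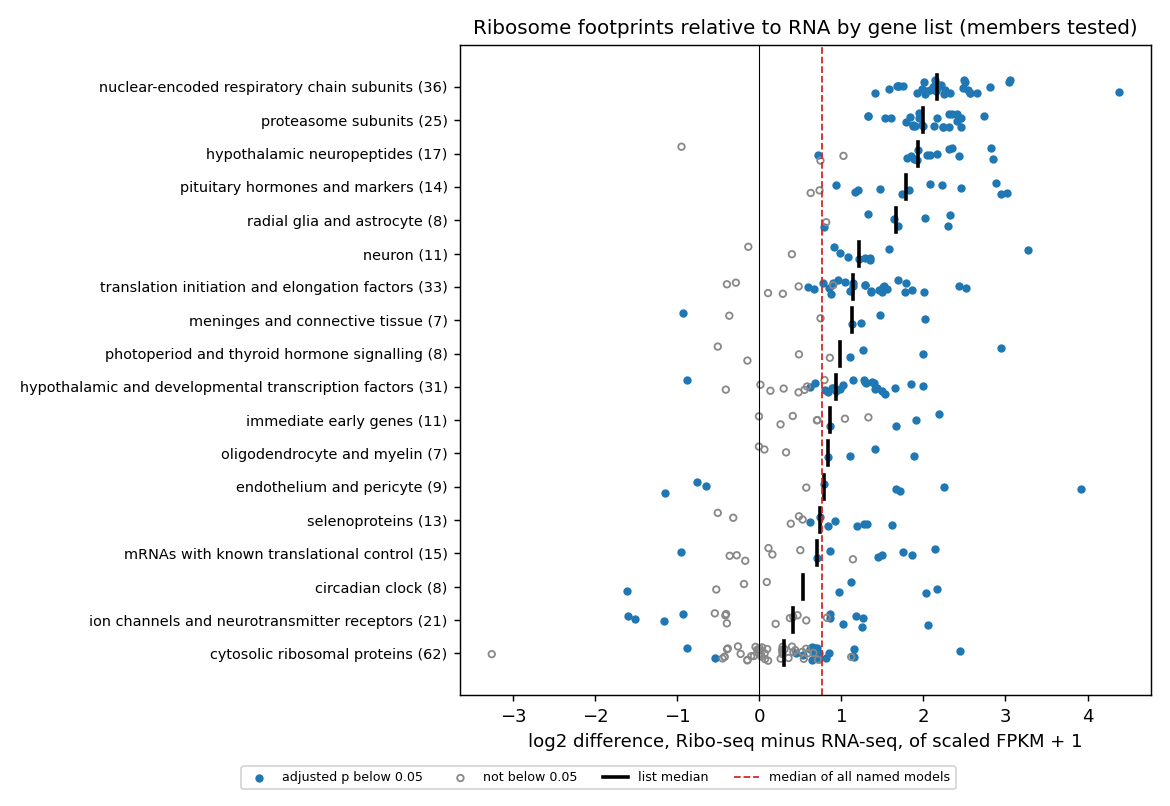
Log2 difference of Ribo-seq minus RNA-seq (x axis, scaled FPKM plus 1) for each tested member of the 18 gene lists with at least 5 tested members (y axis, number tested in brackets); filled points had an adjusted p below 0.05, black bars are list medians and the dashed line is the median of all named models at 0.77. All 36 respiratory chain and all 25 proteasome members lie to the right of the dashed line, and 7 of 62 ribosomal proteins do.

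Few genes of the photoperiod response were tested. Of 8 tested members of the photoperiod and thyroid hormone list, 4 were called higher, cga and slc16a10 among them, 0 lower and 4 neither; with FPKM as deposited, 3 were called higher and 1 lower. dio2, the enzyme that activates thyroid hormone, had 1.13 ± 0.447 FPKM in RNA-seq and 1.66 ± 1.87 in Ribo-seq (SD, n = 2), a log2 difference of 0.48 that did not pass the test (limma, adjusted p = 0.51). It was 1.43 and called without Ribo-seq replicate 1 (limma, adjusted p = 0.026) and -0.19 without Ribo-seq replicate 2 (adjusted p = 0.62), so that single libraries decide it. lpin2, a phosphatidate phosphatase gene, had 2.03 ± 0.219 and 0.979 ± 0.192 FPKM and a difference of -0.15 (limma, adjusted p = 0.50). No model was matched to tshb or eya3, which are not analysed here. Of 8 circadian clock genes, 4 were higher and 1 lower, against 1 and 2 with FPKM as deposited, where the list's median turned from 0.53 to -0.16. Relative to named models it was -0.24 and then -0.29, so the turn goes with the shared scaling. The kinases csnk1d and csnk1e had differences of 2.17 and 2.03, and per2 one of 1.12. Adjusted over the list alone, 4 members of each list were higher and 0 and 1 lower. Neither list was called against the other named models (camera, adjusted p = 0.82 and 0.48).

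Cell type markers were mostly higher in Ribo-seq under median scaling, as named models were in general, but not with FPKM as deposited. Under median scaling no such list beyond the pituitary and neuropeptide lists was called. Of the tested members, 9 of 11 were higher for neurons, 7 of 8 for radial glia and astrocytes, 4 of 7 for oligodendrocytes and myelin, 5 of 9 (with 3 lower) for endothelium and pericytes, and 4 of 7 (with 1 lower) for meninges and connective tissue; the camera adjusted p was 0.21, 0.075, 0.82, 0.74 and 0.82. In the deposited FPKM without scaling, 1, 2, 0, 2 and 1 members of these lists were called higher and 0, 0, 0, 3 and 2 lower. The radial glia list was called with the replicate number as a block (adjusted p = 0.048), with no filter (0.047), with upper quartile scaling (0.045) and with 1 model per RefSeq gene (0.032). It was not called with an estimated correlation (camera, adjusted p = 0.93). Of the remaining lists with a test, 22 of 31 developmental transcription factors (with 1 lower), 4 of 11 immediate early genes, 7 of 15 mRNAs with known translational control (with 1 lower) and 8 of 13 selenoproteins were higher (adjusted p = 0.20, 0.82, 0.82 and 0.82); with FPKM as deposited, 2, 1, 0 and 0 were higher and 2, 0, 2 and 2 lower. Adjusted over the list alone, 10 neuron, 8 radial glia, 4 oligodendrocyte, 5 endothelium (with 3 lower), 5 meninges (with 1 lower), 24 transcription factor (with 1 lower), 4 immediate early, 7 translational control (with 1 lower) and 8 selenoprotein genes were higher. Camera's direction and the sign of the relative median differed for the photoperiod, endothelium, meninges and selenoprotein lists. Microglia and sex steroid lists had 3 tested members each, of which 2 and 0 were higher and 0 and 1 lower, the erythrocyte list 2 and the skeletal muscle list 1, of which 1 and 1 were higher. The lists of mitochondrially encoded proteins, photoreceptors, histones and noncoding RNAs had 0 tested members.

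Transcript models that match long noncoding RNA genes carried few footprints. Of 320 such models, 149 were called lower and 36 higher in Ribo-seq, with a median log2 difference of -0.87, whereas of 9610 models matched to protein-coding genes 804 were lower and 4679 higher, with a median of 0.70 (camera of the former class, p = 3.9e-30, and p = 0.0047 with an estimated correlation). The 39324 models without a RefSeq match had a median of -0.65, with 15948 lower and 6844 higher. Median RNA-seq FPKM was 3.83, 5.35 and 5.32 in the 3 classes, and median Ribo-seq FPKM was 0.742, 5.23 and 1.47. This comparison was added after the data were seen.

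**Figure D2:**
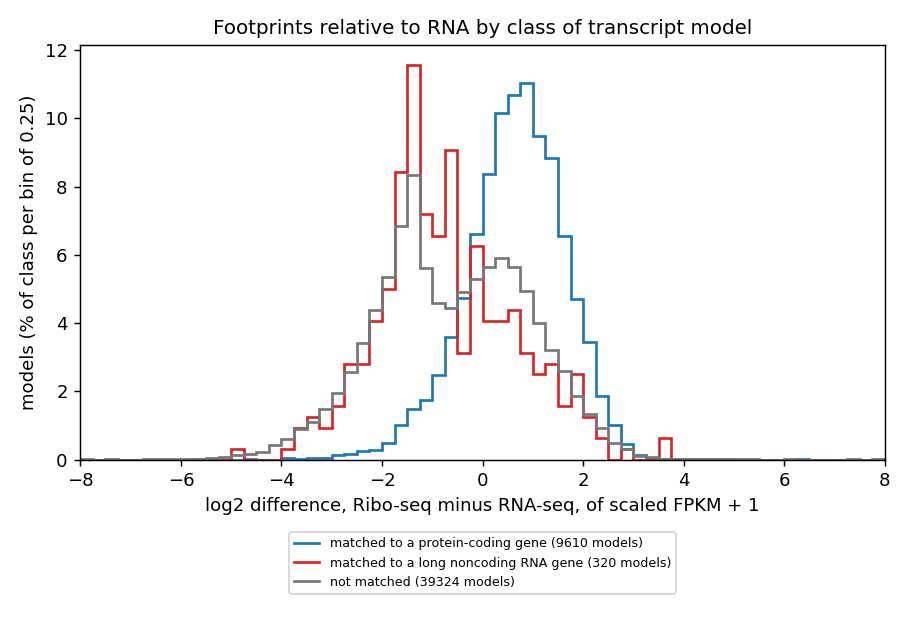
Share of the models of each class (y axis, % per bin of 0.25) by log2 difference of Ribo-seq minus RNA-seq (x axis, scaled FPKM plus 1), for models matched to protein-coding genes, matched to long noncoding RNA genes and not matched. The medians are 0.70, -0.87 and -0.65.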

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

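Fits of 1 model per RefSeq gene and names at 80% overlap were chosen after the data were seen. The pseudocount and the variance trend kept all 4 counts of calls within 1.5 times. With FPKM as deposited, 2425 models were higher, 2248 by at least 2-fold. With no filter, 29544 were lower; at a mean FPKM of at least 5, 4477 were lower, 3997 by at least 2-fold, from fewer models tested. With 1 model per RefSeq gene (fewer tested), 3318 were higher and 2572 lower, 1439 and 1310 by at least 2-fold. The scaling factors were then estimated from these models alone, and the median of named models fell from 0.77 to 0.20. These counts thus hold a change of models and of scaling at once. With 1 library left out, the lone sample was assumed to vary like the other assay; counts ranged from 1529 to 16410 higher, 9458 to 17897 lower, 1525 to 13031 at least 2-fold higher and 8834 to 16605 at least 2-fold lower, the lowest without an RNA-seq library. With the replicate number as a block, 11131 were higher and 16488 lower; deviations of same-numbered libraries correlated at 0.068 (0.098 at a mean FPKM of at least 5), and neither this nor the labels shows whether they share tissue. The block ended the call of the ion channel list and gave one for the radial glia list (adjusted p = 0.064 and 0.048). Of the 18 lists, 7 were called, 3 at a mean FPKM of at least 5, 4 with names at 80% overlap, 0 with an estimated correlation, and 3 to 7 with a library left out (3 without Ribo-seq replicate 1). The correlation of the assays was 0.663 with no filter, 0.299 at a mean FPKM of at least 5 and 0.478 to 0.504 with a library left out. Where not named, the cause was not tested.

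The 7 called lists kept the sign of their medians relative to named models wherever one was computed. Uncalled medians that changed sign were those of myelin (-0.0095 with pseudocount 0.1, -0.022 at a mean FPKM of at least 5, -0.0070 as deposited, -0.00076 with 1 model per RefSeq gene), meninges (-0.30 at a mean FPKM of at least 5), immediate early genes (-0.088 at that filter) and selenoproteins (0.0077 as deposited). With a library left out, the medians ranged from -0.040 to 0.19 for myelin, -0.033 to 0.052 for endothelium, -0.35 to 0.48 for immediate early genes, -0.15 to 0.029 for translational control and -0.088 to 0.17 for selenoproteins. With FPKM as deposited, log2 differences turned to -0.28 for ifrd1, -0.16 for rps15, -0.19 for rps15a, -0.58 for scn3b, -0.41 for vamp2 and -0.075 for xbp1, and with 1 model per RefSeq gene to -0.19 for ifrd1, -0.072 for rps15, -0.097 for rps15a, -0.50 for scn3b and -0.32 for vamp2. That of scn3b was -0.055 with upper quartile scaling. Each of these settings changes the scaling of all models together. The median of named models, 0.77, was 0.13 with FPKM as deposited, 0.20 with 1 model per RefSeq gene and 0.56 with upper quartile scaling. These turns of single genes therefore reflect the shared scaling. With a library left out, they ranged from -0.19 to 1.43 for dio2, -0.16 to 0.31 for hsd17b3, -0.014 to 0.59 for scn3b and -0.44 to 0.010 for selenop. The cause of the other changes of sign was not tested. Depth is unknown, so what it limits cannot be given.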

Other observations

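The tests in this part were chosen after the data had been seen; what each explanation predicts was written before the matched lists were computed, except for the length of ribosomal protein models alone. The libraries numbered 2 held more immediate early gene transcripts, which neurons make within minutes of stimulation, than those numbered 1 in both assays. In RNA-seq, 10 of the 11 tested genes were higher in replicate 2, with a median log2 difference of 0.53 against 0.09 for lists matched on mean FPKM. In Ribo-seq, 10 of 11 were also higher, with a median of 0.60 against 0.18. egr1 had 21.4 and 29.7 FPKM in RNA-seq replicates 1 and 2 and 38.1 and 82.8 in Ribo-seq, and npas4, picked out after its values were seen, had 9.62 and 15.5 and then 2.67 and 17.2. These FPKM are before scaling. The factors of Ribo-seq replicates 1 and 2 were 0.651 and 0.925, so part of the gap within Ribo-seq is a difference in scale. The list's median lay at percentile 100 of 10000 matched lists in each assay, which describes these libraries and, with 1 library on each side, is not a test. Among the 18 lists examined, hypothalamic neuropeptides had percentiles of 95.9 in RNA-seq and 99.99 in Ribo-seq, neuron markers 99.8 and 90.8, and ion channels and receptors 79.0 and 98.9. Selenoproteins had 99.2 and 11.5, respiratory chain subunits 5.14 and 96.3, pituitary hormones and markers 2.05 and 30.8, and ribosomal proteins 0.33 and 2.51. Developmental transcription factors had 0.01 and 40.5 and photoperiod genes 14.7 and 0.32, so that replicate differences were not specific to neuronal lists.

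The most abundant model by footprints carries no name. It lies on chromosome 13 from 2561241 to 2564296, has a small nuclear RNA gene within its span, and had 248935 and 204978 FPKM in the Ribo-seq libraries and 14322 and 8350 in the RNA-seq libraries. An unmatched model on chromosome 14, 7809480 to 7818449, had 43440 FPKM in Ribo-seq replicate 1 and 4897 in replicate 2. The most abundant model by RNA, on chromosome 10 from 12317380 to 12317583, had 51207 and 46306 FPKM in RNA-seq and 2739 and 1821 in Ribo-seq.

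Ribosomal protein genes had fewer footprints for their RNA than other named models, with a median log2 difference of 0.29 over 62 genes against 0.77, a list call lost with an estimated correlation (adjusted p = 0.93). A high RNA level as such is argued against: named models matched on RNA-seq FPKM had a median of 1.87, and 0 percent of 10000 matched lists were as low as the ribosomal proteins. Short length is argued against in the same way, since named models matched on length and RNA level had a median of 1.95, again with 0 percent as low. Untranslated ends within the models stay open: matched models whose length is not a multiple of 3 had a median of 1.92, but that property did not separate named models (medians 0.77 and 0.77), so the prediction made from it decides nothing. Reads shared between gene copies stay open too, untested without the genome sequence, and with a single condition in the design, no biological explanation was tested.

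Long noncoding RNA models carried few footprints, with a median log2 difference of -0.87 over 320 models. A low RNA level combined with limited footprint depth is argued against, because protein-coding models matched on RNA-seq FPKM had a median of 0.63 and 0 percent of 10000 matched sets were as low. Short length is argued against too: with length also matched, the median was 0.62 and again 0 percent were as low. Among models with a mean RNA-seq FPKM of at least 10, the medians were -0.71 for 59 long noncoding and 1.20 for 2516 protein-coding models. Of these long noncoding models, 15 were called higher and 21 lower, against 1716 and 185 of the protein-coding ones, so the noncoding class was mixed. Whether these RNAs are bound by few ribosomes was not itself tested, and errors in matching models by position stay open, untested. With a single condition, no biological explanation was tested.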
